A study of Caenorhabditis elegans with 4 samples.

How the data were processed

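RNA was measured by paired-end sequencing, with reads of 100 bp, in adult Caenorhabditis elegans of the wild-type strain N2. There were 4 libraries, 1 for each combination of RNAi food (empty vector as control, or elt-2) and oxygen (normoxia, or 36 h at 0.5% oxygen in nitrogen, begun at day 1 of adulthood). RNAi by feeding gives animals bacteria that make double-stranded RNA of the target gene. The libraries shared a sequencing lane, per the labels' protocols. Groups were taken from the sample titles.

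Gene values were deposited by the authors as RPKM (reads per kilobase of transcript, scaled to the mapped reads), per the file headers, in 6 tables that each set 1 library against another. Each of the 4 libraries had the same values in every table that held it, with 0 differing values. The submitters' processing notes name TopHat2 2.0.8b, Cufflinks 2.1.1 and the genome build ce10, without saying what each was used for. The annotation, the read filters and the treatment of strand are not given in the sources used here. Each deposited table also holds a p-value and an FDR-adjusted p-value per gene from the authors' own test of 1 library against 1 library, per the file headers, and a call of significance. Those calls compare libraries, not conditions, and are credited where printed.

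FPKM had been assumed when the tests were fixed, and the headers name RPKM. The tests on a log scale fit both units and were kept. Each table had 19852 loci. Of these, 14777 matched a current transcript by accession and 17548 had a current symbol in the name tables of the WBcel235 assembly, used for names and transcript lengths only. Descriptive names of 240 loci were replaced by the current symbol. Other names are as deposited, with the current symbol given where it differs. Coordinates are those of the files, counted from 1, on ce10.

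Log2 ratios were computed as log2 of (RPKM + 1) over (RPKM + 1), which understates the change of genes with low values. Genes were compared where the mean over the 4 libraries was at least 1 RPKM, the locus named 1 gene and no table gave it the status FAIL, HIDATA or LOWDATA. This left 10655 genes. The status removed 8 loci, among them vit-2, vit-5 and vit-6, and 334 loci named several genes. Those vitellogenins were listed at 0 in every library but the normoxia one labelled elt-2 RNAi, where they were at 3159, 3176 and 4921 RPKM. With 1 library per group, the 4 pairwise comparisons and the difference of hypoxia effects have no test, and genes past 2-fold were counted. An average effect of hypoxia over both RNAi groups, and of RNAi over both oxygen levels, was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) of all 4 libraries, with additive terms, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom, which is the interaction of oxygen and RNAi. A gene whose hypoxia effect differs between RNAi groups therefore counts as variable. Nothing in the labels says that the libraries came from separate cultures, so these p-values measure only the spread between these 4 libraries.

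Genes were named by a rule fixed before the data were examined. It took elt-2 first, then the 10 genes with the highest and the 10 with the lowest ratio of each comparison among genes with a mean of at least 5 RPKM, and 5 each way for the difference of hypoxia effects. Of each gene list it took the 2 to 4 members with the largest absolute ratio, or all members of lists with 10 or fewer. In total 37 lists were fixed in advance, covering hypoxia, iron, digestion, immunity, stress, metabolism, detoxification, structural and cell cycle genes and markers of cell types. Of these, 35 had at least 3 compared loci. Coelomocyte markers had 1, cup-4, with log2 ratios of 0.16 and -0.01 for hypoxia in the libraries labelled control and elt-2 RNAi, and no locus matched the mitochondrially encoded genes. The median of each list was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. A percentile of 2.5 or less, or 97.5 or more, is called apart from random lists, as a description of these libraries.

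The total number of reads is not given in the sources used here. RPKM of low genes lie on steps set by single reads. Comparing these steps among genes under 0.3 RPKM put the value of 1 read, relative to the control RNAi normoxia library, at 0.996 in control RNAi hypoxia, 1.09 in the normoxia library labelled elt-2 RNAi and 0.873 in the hypoxia library labelled elt-2 RNAi. The search covered only a limited range of ratios around equal depth, so a larger difference could not have been found. Within that range relative depth differed little, and absolute depth is unknown, so no interval for counting error is given.

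Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter on low values, a mean of at least 5 RPKM, ratios centred on the median gene, loci naming several genes kept, the status OK only, a threshold of 4-fold, and limma without the trend. A lowess trend on transcript length removed from the ratios, and genes listed at 0 in any library left out, were added after the data were seen. Transcript length was known for 97.3% of the genes compared. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for the hypoxia effect in control RNAi, with 200 genes changed among 10727 and a noise SD of 0.3 on the log2 scale. Of the planted changes of 1.5, 92% passed 2-fold and limma called 95%, and of those of 3, 100% passed and limma called 100%. Among the unchanged genes, 95 were past 2-fold higher and 106 past 2-fold lower, and limma called 6. Of 200 random lists of 20 genes, 3% stood apart, and of 50 lists shifted by 0.5, 100% did. The simulated noise was independent and equal for all genes, and the planted changes were the same in both RNAi groups. The simulated lists held unrelated genes. The simulation thus checks the steps and does not give the error of limma or of the list percentiles in these data.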

Results

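Whole-animal RNA of adult C. elegans, exposed from day 1 of adulthood, was profiled in 4 libraries, 1 per group, so that no value below has a replicate error and no pairwise difference has a replicate check. The question was how 36 h of hypoxia at 0.5% oxygen changed gene expression, and how feeding RNAi against elt-2, a GATA transcription factor of the intestine, changed it at each oxygen level. At least 1 RPKM was listed for 10605 loci in control RNAi normoxia, 11048 in control RNAi hypoxia, 10462 in the normoxia library labelled elt-2 RNAi and 10775 in the hypoxia library labelled elt-2 RNAi. Ribosomal protein genes held 18.9%, 24.5%, 18.7% and 24.1% of the summed RPKM in that order.

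The targeted gene went against its label. elt-2, on chromosome X from 10481180 to 10483367 (ce10, plus strand), was listed at 4.81 RPKM in control RNAi normoxia and 15.2 in control RNAi hypoxia, and at 14.3 and 23.8 RPKM in the normoxia and hypoxia libraries labelled elt-2 RNAi. Its log2 ratio of labelled elt-2 RNAi over control was 1.40 in normoxia and 0.62 in hypoxia. The values therefore do not show a lower elt-2 transcript level in the libraries labelled elt-2 RNAi, and every direction given for RNAi below rests on the labels. For elt-2, limma put the average hypoxia effect at 1.09 ± 0.23 (SE, 4 libraries; adjusted p = 0.0423) and the average RNAi effect at 1.01 ± 0.23 (adjusted p = 0.224). Both averages include the libraries labelled elt-2 RNAi, where double-stranded RNA from the food bacteria may raise the elt-2 value. With 1 residual degree of freedom, the SE also rests on the mean-variance trend over other genes. The authors' own test called elt-2 in none of the 4 comparisons.

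**Figure D1:**
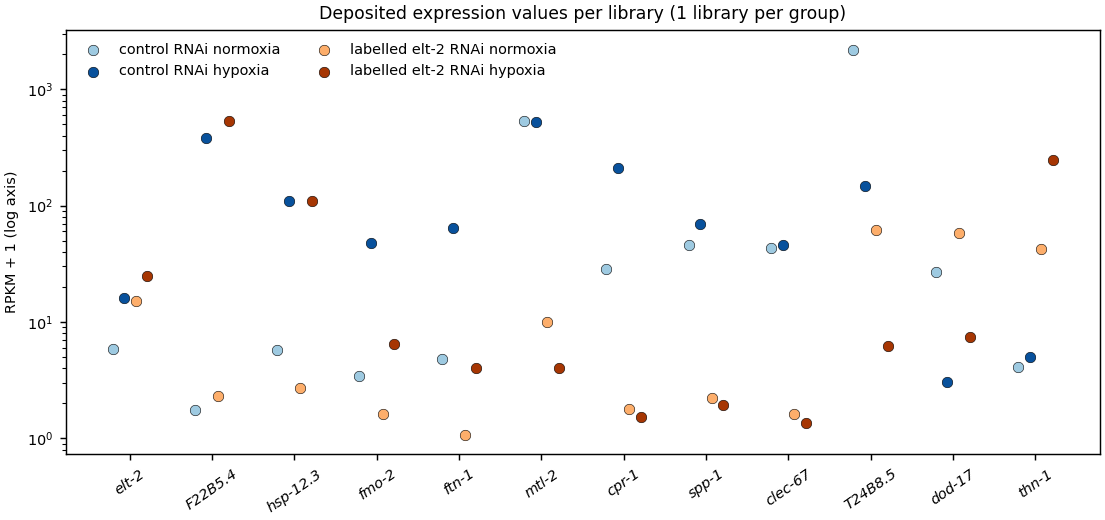
RPKM + 1 on a log axis for 12 genes, with 1 point for each of the 4 libraries and no error, since each group has 1 library. elt-2 lay higher in both libraries labelled elt-2 RNAi (14.3 and 23.8 RPKM) than in the control at the same oxygen level (4.81 and 15.2 RPKM), while mtl-2, cpr-1, spp-1 and clec-67 lay lower.

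In control RNAi, the highest ratio under hypoxia was that of F22B5.4, a gene known to depend on the hypoxia-inducible factor HIF-1, at 0.734 RPKM in normoxia and 384 in hypoxia (chromosome II, 8449650 to 8452628). The small heat shock gene hsp-12.3 was at 4.7 and 108 RPKM, the C-type lectin clec-47 at 2.82 and 69.8, the cytochrome P450 cyp-32B1 at 2.01 and 54.6, and Y40B10A.6 (now comt-4) at 7.6 and 256. C29F7.2 was at 2.9 and 70.6, C08E8.3 at 3.04 and 72.9, and Y38E10A.15 (now nspe-7) at 0.625 and 30.7. C36A4.10 and ZK742.6 were listed at 0 in normoxia and at 25.3 and 19.1 RPKM in hypoxia. In all, 1010 of 10655 genes were at least 2-fold higher and 378 at least 2-fold lower. Only 655 genes were that much higher among those with a mean of at least 5 RPKM. In the authors' deposited table for this pair, 61 loci were called significant, 50 of them higher in hypoxia. Of the 10 genes named above, Y40B10A.6, cyp-32B1 and C29F7.2 were called and the others were not. F22B5.4 had an adjusted p of 0.261 in the authors' test.

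Among the 10 lowest ratios in control RNAi, the nspa peptide genes nspa-8, nspa-4 and nspa-5 were at 257, 47.2 and 58 RPKM in normoxia and at 5.04, 0.759 and 5.66 in hypoxia, a multigene family whose reads may be split between copies. T24B8.5 (now sysm-1), an innate immune reporter gene on chromosome II from 9082621 to 9083081, was at 2203 and 146 RPKM. The infection-response gene F35E12.5 (irg-5) was at 26.8 and 2.4, F55G11.4 (now mbug-1) at 71.1 and 5.49, and dod-17 at 26 and 2.07. T22B7.7 was at 186 and 14.7, fip-2 at 25 and 0.606, and F15E6.4 at 19.5 and 1.49. Of these 10 genes, the authors' test called T24B8.5, T22B7.7 and F55G11.4 only.

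Iron and haem handling genes stood highest among the fixed lists in control RNAi, with 6 of 8 at least 2-fold higher and a median log2 ratio of 2.51 (percentile 100). The ferritin ftn-1 was at 3.75, the metal transporter smf-3 at 3.23, C15C8.3 (hrg-7) at 3.20, the haem transporters hrg-1 and hrg-4 at 3.05 and 1.97, the iron exporter homologue fpn-1.1 at 1.61, ftn-2 at 0.75 and smf-1 at 0.07. HIF-1-dependent genes did not move as one, with 4 of 9 at least 2-fold higher, 2 lower and a median of 0.39 (percentile 91.6). Beside F22B5.4 at 7.79, fmo-2 was at 3.79, the prolyl hydroxylase gene phy-2 at 1.58 and oac-54 at 1.38, whereas sqrd-1, which oxidizes sulfide, was at -1.57 and rhy-1 at -1.22. The HIF-1 hydroxylase gene egl-9 was at 0.33, nhr-57 at 0.39 and cysl-2 at 0.29. With a trend on transcript length removed, the median of these HIF-1-dependent genes was 0.53 (percentile 97.8). Cytosolic heat shock genes had a median of 0.64, with 6 of 18 at least 2-fold higher, the hsp-16 pairs being near-identical copies.

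In control RNAi hypoxia, of 12 aspartic and cysteine digestive proteases, 6 were at least 2-fold higher (median 1.06, percentile 100), led by cpr-1 at 2.90 and by asp-5 and cpr-5, both at 1.91. Fatty acid synthesis, elongation and desaturation genes had a median of 0.50 (percentile 98.9) and went both ways. The desaturases fat-3, fat-6 and fat-4 were at 3.20, 2.36 and 2.18, while fat-5 and fat-7 were at -1.63 and -1.21. Lipolysis and beta-oxidation genes had a median of 0.58 (percentile 99.8), with ech-9 at 3.98, acs-2 at 2.52 and acdh-1 at -1.98, and this list lay inside the random range with no filter on low values (median 0.16). Intestinal immune effectors had a median of 0.35 (percentile 98.5), with 5 of 20 at least 2-fold higher and 1 lower.

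In the same comparison, sperm markers had the lowest median of all lists, -1.54, with 13 of 15 at least 2-fold lower, most being msp genes of near-identical sequence and low values. Embryo markers had a median of -1.36, with 6 of 8 at least 2-fold lower. Among these, tbx-38 had the lowest ratio, at 2.81 RPKM in hypoxia, and tbx-37, skr-9, skr-10, skr-8 and skr-7 were at log2 ratios of -1.92, -1.66, -1.49, -1.23 and -1.07, while pha-4 and hlh-1 were at 0.92 and 0.83. Germline and oocyte markers had a median of -0.56 with none of 20 past 2-fold, oma-2 at -0.85 being the lowest. DNA replication and cell cycle genes had a median of -0.68, with the cyclin cyb-3 at -1.09. The vitellogenins vit-3, vit-4 and vit-1, which encode yolk proteins, were at -1.32, -1.26 and -0.85, the first of these sharing most of its sequence with vit-4. Epidermal antimicrobial peptides had a median of -0.83, with 4 of 13 at least 2-fold lower, including cnc-4 at -2.25 and cnc-7 at -2.16. Cuticle collagens had a median of -0.44, with 16 of 46 at least 2-fold lower, and proteasome subunits one of -0.32.

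Body wall muscle, neuron and intestine markers stood apart above random lists, and epidermis and pharynx markers did not. Body wall muscle markers had a median of 0.86, with mlc-2 at 315 RPKM in normoxia and 890.5 in hypoxia, and log2 ratios for lev-11 of 1.21, unc-15 of 1.04, act-4 of 0.99, cpn-3 of 0.94, mlc-1 of 0.77, unc-27 of 0.45, myo-3 of -0.00, unc-89 of -0.20 and unc-52 of -0.26. Neuron markers had a median of 0.58 (6 of 35 at least 2-fold higher) and intestine markers one of 0.77 (6 of 14), with ifb-2 at 1.89 and ifd-2 at 1.86. Epidermis markers had a median of 0.47 (percentile 80.0), with wrt-10 at 1.78, sqt-3 at 1.35, elt-3 at 0.47, col-19 at 0.11 and grd-10 at -0.73. The 3 compared pharynx markers had a median of -0.30 (percentile 19.3), with mlc-1 shared with muscle, tni-4 at -0.30 and phat-6 listed at 5.69 RPKM in normoxia and 0 in hypoxia. Ribosomal protein genes had a median of 0.54, which was 0.29 once a trend on transcript length was removed.

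In the libraries labelled elt-2 RNAi, 1052 genes were at least 2-fold higher in hypoxia and 453 at least 2-fold lower. F22B5.4 again had a high ratio, at 1.3 RPKM in normoxia and 536 in hypoxia, and hsp-12.3 was at 1.73 and 108. Also among the 10 highest were F58E6.7 (hrg-3) at 0.186 and 37.4 RPKM and C15C8.3 (hrg-7) at 23.8 and 513. B0205.13 was at 1.57 and 90.7, W02A2.9 at 94.6 and 1824, clec-221 at 1.03 and 36.2, C07G1.7 at 0.152 and 18.7, and F58G6.9 (now chca-1) at 4.55 and 91.3. A copy of F46A8.7 was listed at 0 in normoxia and 950.3 RPKM in hypoxia. Its locus, on chromosome I from 11238109 to 11238219, is little longer than a read of 100 bp. The authors' test gave it an adjusted p of 0.740. The lowest ratios were those of nspa-8 (408 and 3.27 RPKM), nspa-4 (69.6 and 3.37), nspa-5 (50.6 and 2.09) and F56C3.8 (80.6 and 0.741). The fatty acid and retinol binding gene far-3 was at 107 and 3.62, the glutathione S-transferase gst-4 at 51.9 and 2.4, F48C1.9 at 22.1 and 0.264, fip-6 at 23.1 and 0.703, F15E6.4 at 31 and 1.47, and D1086.3 at 142 and 10.2. In the authors' deposited table for this pair, 91 loci were called significant, 69 of them higher in hypoxia. Of the genes named above, only C15C8.3, F58G6.9 and D1086.3 were called.

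Iron and haem handling genes again stood highest among the lists (median 1.85, 7 of 8 at least 2-fold higher), with hrg-7 (C15C8.3) at 4.37, hrg-1 at 3.12, hrg-4 at 2.08, ftn-1 at 1.92, ftn-2 at 1.78, smf-3 at 1.74, fpn-1.1 at 1.40 and smf-1 at 0.11. Here ftn-1 was at 0.0692 RPKM in normoxia and 3.06 in hypoxia, so the pseudocount understates its change. HIF-1-dependent genes had a median of 1.09 (percentile 99.8), with fmo-2 at 1.99, phy-2 at 1.70, oac-54 at 1.32, cysl-2 at 1.09, egl-9 at 0.14, nhr-57 at 0.07, rhy-1 at -0.82 and sqrd-1 at -1.46. Gene by gene, their median difference from control RNAi was only 0.07 (percentile 68.4). Digestive proteases had a median of 0.49, cytosolic heat shock genes 0.69 and fatty acid synthesis genes 0.84. Lower medians were those of embryo markers (-1.26), epidermal antimicrobial peptides (-1.16), cuticle collagens (-0.98), sperm markers (-0.94), cell cycle genes (-0.49), germline markers (-0.38), gluconeogenesis, glyoxylate, trehalose and glycogen genes (-0.36), proteasome subunits (-0.30) and C-type lectins (-0.27). Of these, gluconeogenesis genes lay inside the random range with the length trend removed (-0.22), and C-type lectins with a mean of at least 5 RPKM. Muscle markers had a median of 0.82, neuron markers 0.52, intestine markers 0.98, ribosomal protein genes 0.51 and epidermis markers 0.38 (percentile 77.2). Vitellogenins (-0.19, percentile 21.1), intestinal immune effectors (-0.21, percentile 4.04), beta-oxidation genes (-0.08, percentile 36.8), endoplasmic reticulum chaperones (0.27, percentile 94.8) and pharynx markers (-0.08, percentile 40.5) lay inside the range of random lists. With a trend on transcript length removed, endoplasmic reticulum chaperones stood above that range (0.34, percentile 99.5). The vitellogenin median uses the normoxia library in which alone vit-2, vit-5 and vit-6 had values.

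The hypoxia effects in control RNAi and in the libraries labelled elt-2 RNAi share no library. Past 2-fold, 624 genes were higher in both, where independent lists would share 99.7, and 245 were lower in both. Only 13 genes went past 2-fold in opposite directions, and Spearman's rho across genes was 0.81, genes not being independent replicates. Averaged over both RNAi groups, limma called 3510 genes at an adjusted p of 0.05 or less, 1833 higher and 1677 lower in hypoxia. F22B5.4 had an average log2 ratio of 7.83 ± 0.09 (SE; limma adjusted p = 0.00311), hsp-12.3 of 4.79 ± 0.30 (adjusted p = 0.0143), T22B7.7 of -3.52 ± 0.08 (adjusted p = 0.0111) and T24B8.5 of -3.62 ± 0.16 (adjusted p = 0.0143). Each of these 4 genes moved the same way in both RNAi groups. The fit favours such genes, since it counts a difference between RNAi groups as error, so this agreement is not separate evidence. The authors' test called T22B7.7 in both groups, T24B8.5 in control RNAi only, and F22B5.4 and hsp-12.3 in neither. Without the mean-variance trend limma called 2182 genes, and with no filter on low values 2215.

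**Figure D2:**
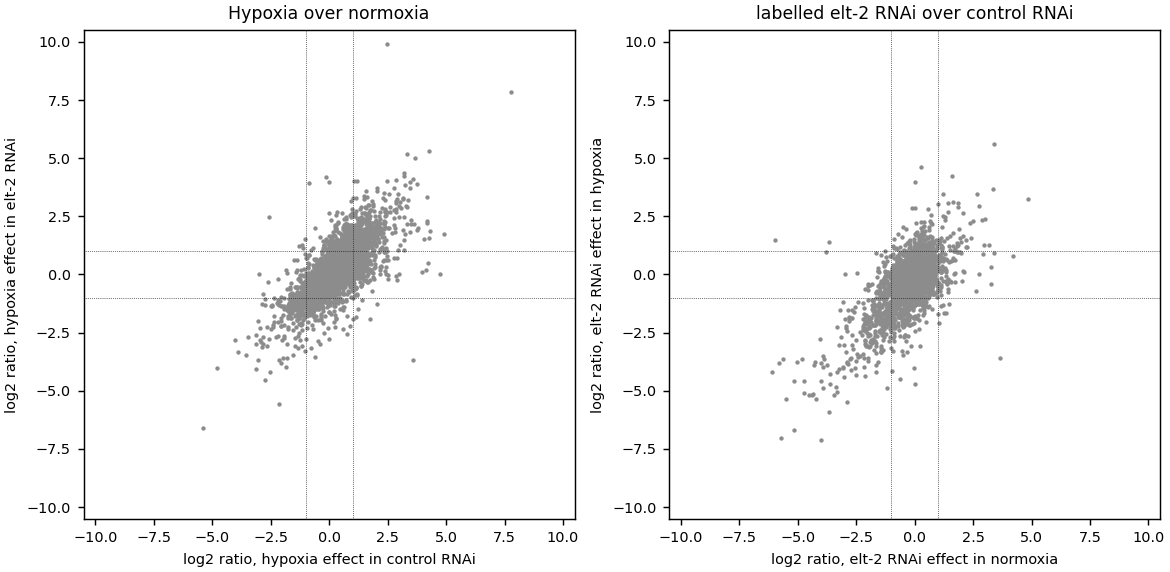
Log2 ratios of 10655 genes, 1 point per gene, with dotted lines at 2-fold. Left, hypoxia over normoxia in the libraries labelled elt-2 RNAi against control RNAi (Spearman's rho 0.81 across genes), and right, labelled elt-2 RNAi over control in hypoxia against normoxia (rho 0.43).

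In normoxia, 390 of all compared genes were at least 2-fold lower in the library labelled elt-2 RNAi than in the control, and 131 at least 2-fold higher. The metallothionein mtl-2 (chromosome V, 14018257 to 14018628) was at 529 RPKM in control and 9.01 in labelled elt-2 RNAi, T24B8.5 at 2203 and 60.8, and the lectins clec-85 and clec-209 at 337 and 526 against 6.52 and 17.9. F56A4.2, which resembled clec-209 in every library, was at 616 and 18, F49F1.1 (now drd-50) at 74 and 0.101, C32H11.9 (now cld-1) at 55.6 and 0.15, and the enoyl-CoA hydratase ech-7 at 50.1 and 0.452. dod-21 was listed at 55.4 RPKM in control and at 0 in labelled elt-2 RNAi, and a copy of F46A8.7 at 61.1 and 0. Higher in labelled elt-2 RNAi were the thaumatin-like gene thn-1 (3.07 and 41.3 RPKM), F58F12.4 (now glam-3; 1.14 and 20.6), C26F1.1 (0.9 and 17.3), C43D7.7 (1.99 and 23.2), Y75B8A.28 (4.12 and 39.1) and F56C3.8 (3.38 and 80.6). ZK742.6, Y38H6A.5, Y105C5A.12 and fipr-20 were listed at 0 in control and at 9.49, 27.7, 8.06 and 11.7 RPKM in labelled elt-2 RNAi. In the authors' deposited table for this pair, 67 loci were called significant, 63 of them lower in the library labelled elt-2 RNAi. Of the genes named above, T24B8.5, dod-21, mtl-2, clec-85, F56A4.2 and clec-209 were called, all lower. None of the higher genes named above was called.

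Digestive proteases had the lowest median among the lists in this comparison, -2.46, with 8 of 12 at least 2-fold lower and 2 higher. cpr-1 was at 27.3 RPKM in control and 0.775 in labelled elt-2 RNAi, and cpr-3 the other way at 17.3 and 41. The log2 ratios of cpr-5, asp-2 and cpr-6 were -3.98, -3.22 and -3.06. Of the iron and haem handling genes 4 of 8 were at least 2-fold lower, with the median at percentile 0 and hrg-7 (C15C8.3) at -2.56, ftn-1 at -2.17, hrg-4 at -2.13, hrg-1 at -1.70, smf-3 at -0.70, fpn-1.1 at -0.54, ftn-2 at 0.24 and smf-1 at 0.25. Intestinal immune effectors had a median of -1.01, with 10 of 20 at least 2-fold lower and 4 higher, among them clec-67 at -4.73 and the saposin-like spp-1 at -4.37. Vitellogenins had a median of -0.95, intestine markers one of -0.51 with mtl-1 at -2.21 and ges-1 at -1.34, and C-type lectins one of -0.16 with 16 of 62 at least 2-fold lower. The vitellogenin median uses the only library with values for vit-2, vit-5 and vit-6, so this family was not quantified alike in the 2 libraries. Embryo and sperm markers had medians of -0.75 and -0.55. Epidermal antimicrobial peptides had a median of 0.69 (3 of 13 at least 2-fold higher), with cnc-6 at 1.66, nlp-30 at 1.36 and nlp-34 at 1.11, and germline markers one of 0.16. Muscle and neuron markers had medians of -0.12 and -0.16, and HIF-1-dependent genes one of -0.23. Fatty acid synthesis (-0.19) and beta-oxidation genes (-0.18) and endoplasmic reticulum chaperones (-0.12) were also at or under percentile 2.5.

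In hypoxia, 541 genes were at least 2-fold lower in the library labelled elt-2 RNAi than in the control, and 207 at least 2-fold higher. cpr-1, a cathepsin B-like protease, was at 209.9 RPKM in control and 0.526 in labelled elt-2 RNAi, mtl-2 at 520.2 and 3.04, ech-7 at 169 and 0.645, and the lysozyme lys-4 at 155 and 1.63. The aspartic protease asp-13 was at 107 and 1.4, clec-85 at 297 and 6.22, K08D8.5 at 66.8 and 0.679, cyp-35A3 at 42.1 and 0.18, spp-1 at 68.7 and 0.927, and the cathepsin-like F32H5.1 at 113 and 2.19. The higher genes were thn-1 (3.98 and 245 RPKM), clec-221 (0.495 and 36.2), phg-1 (0.159 and 20.7), F58F12.4 (1.53 and 31), F15B9.6 (5.94 and 76.2), the cadmium-response gene cdr-4 (49.3 and 419), C49C3.9 (55.3 and 460.2), T19C9.8 (9.57 and 80.1) and F56C3.9 (log2 ratio 2.91). Y38H6A.5 was listed at 0 in control and 8.45 RPKM in labelled elt-2 RNAi. In the authors' deposited table for this pair, 106 loci were called significantly lower in the library labelled elt-2 RNAi and 13 higher. Of the lower genes named above, cpr-1, asp-13, clec-85 and F32H5.1 were called. Of the higher ones, thn-1, F15B9.6, cdr-4, C49C3.9 and T19C9.8 were called.

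Intestinal immune effectors had a median of -1.59 in that comparison, with 15 of 20 at least 2-fold lower, and digestive proteases one of -2.32 with 8 of 12. Iron and haem handling genes had a median of -1.51, with ftn-1 at 63.7 RPKM in control and 3.06 in labelled elt-2 RNAi, and log2 ratios for smf-3 of -2.19, hrg-4 of -2.02, hrg-1 of -1.63, hrg-7 (C15C8.3) of -1.38, fpn-1.1 of -0.74, smf-1 of 0.29 and ftn-2 of 1.27. C-type lectins had a median of -0.55 (26 of 62 at least 2-fold lower), intestine markers -0.46, embryo markers -0.54, cuticle collagens -0.39, beta-oxidation genes -0.36 and fatty acid synthesis genes -0.35. Higher medians were those of epidermal antimicrobial peptides (0.43), endoplasmic reticulum chaperones (0.33), cytosolic heat shock genes (0.29) and germline markers (0.23). Vitellogenins (0.05), sperm markers (-0.16), muscle (-0.05), neuron (-0.07), pharynx (0.26) and epidermis markers (-0.36), and HIF-1-dependent genes (-0.11) were inside the random range. In normoxia pharynx (-0.12) and epidermis markers (-0.28) were inside it too.

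The RNAi effects in normoxia and hypoxia share no library. Lower in both were 286 genes, where 19.8 would be shared by independent lists, and higher in both were 54, where 2.55 would be. In opposite directions went 11 genes, and Spearman's rho across genes was 0.43. Averaged over both oxygen levels, limma called 118 genes, 104 lower and 14 higher in the libraries labelled elt-2 RNAi. Among these, clec-85 had an average log2 ratio of -5.43 ± 0.08 (SE; limma adjusted p = 0.00838), T24B8.5 of -4.86 ± 0.16 (adjusted p = 0.0214), mtl-2 of -6.37 ± 0.34 (adjusted p = 0.0264), and F58F12.4 of 3.50 ± 0.17 (adjusted p = 0.0247), each in the same direction at both oxygen levels. Here too the fit favours genes with like effects at both oxygen levels. The authors' test called clec-85 at both oxygen levels, T24B8.5 and mtl-2 in normoxia only, and F58F12.4 at neither. Without the mean-variance trend limma called 0 genes, with 1397 at an unadjusted p under 0.05, and with no filter on low values 48. The calls of this average thus rest on the trend.

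**Figure D3:**
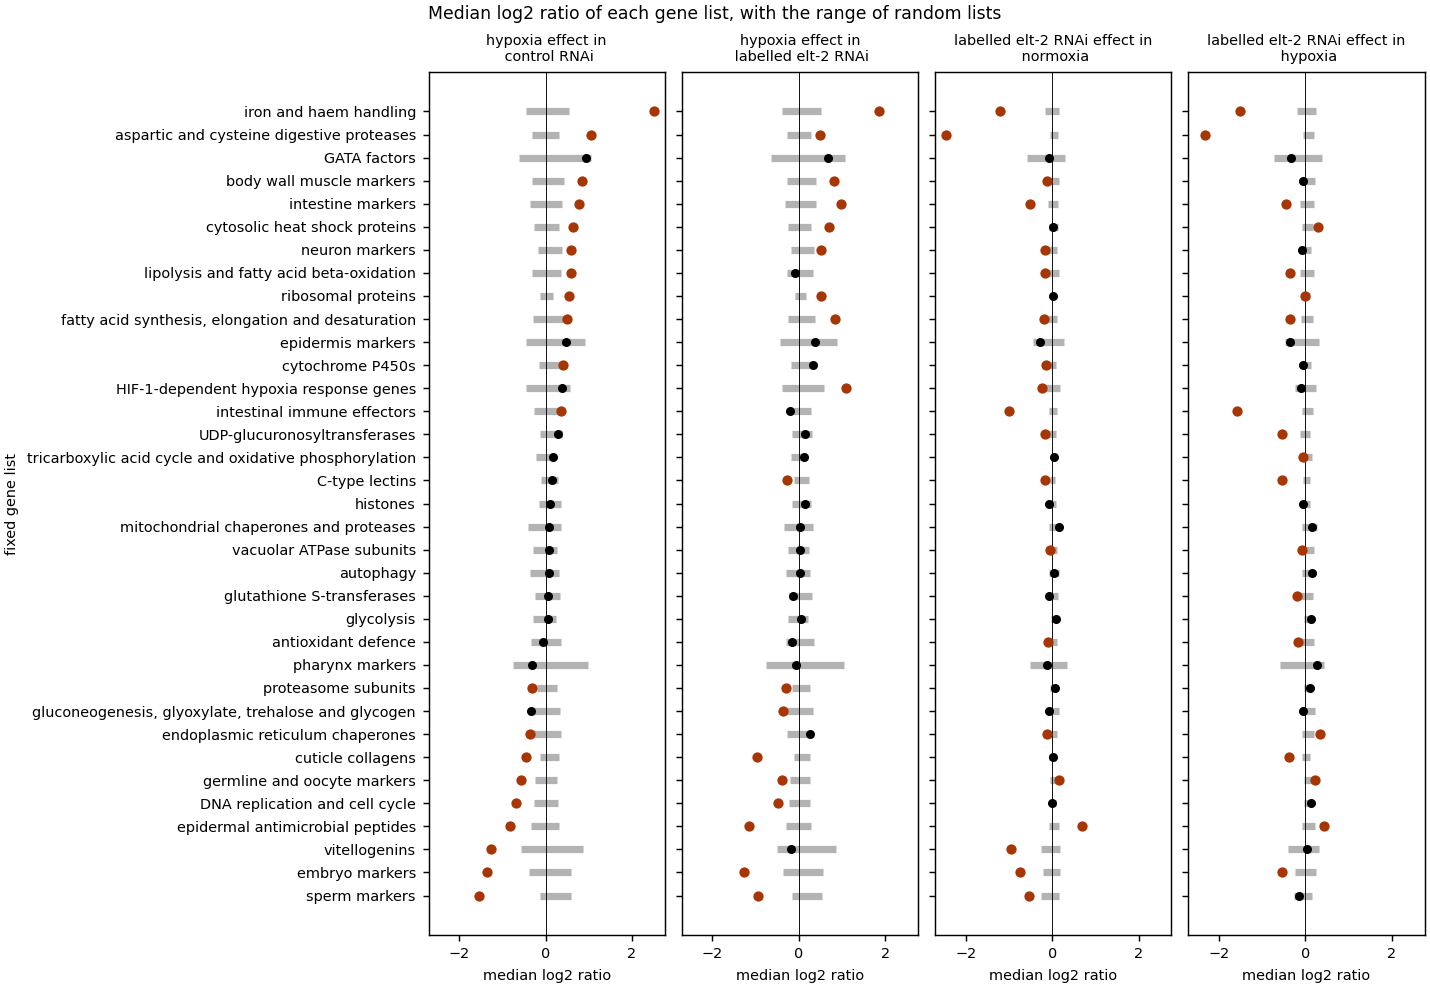
Median log2 ratio of 35 fixed gene lists in the 4 comparisons, with grey bars for the central range of 10000 matched random lists, 2.5% of them lying beyond each end, and coloured points for medians outside it. Digestive proteases lay at 1.06 and 0.49 for hypoxia and at -2.46 and -2.32 for the libraries labelled elt-2 RNAi over control.

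The log2 hypoxia ratio differed between RNAi groups in both directions. Among the 5 genes with the lowest difference, labelled elt-2 RNAi minus control, clec-47 was at 2.82 and 69.8 RPKM in control RNAi normoxia and hypoxia, and at 0.69 and 1.39 in the libraries labelled elt-2 RNAi, and ech-9 was at 0.738 and 26.3 against 0.143 and 0.219. C26F1.1 was at 0.9 and 5.43 against 17.3 and 3.89, and C36A4.10 and fipr-20 had libraries listed at 0. The other way, clec-221 was at 0.657 and 0.495 in control and at 1.03 and 36.2 in labelled elt-2 RNAi, F09C8.1 at 26.4 and 3.57 against 1.17 and 11.1, and Y41C4A.11 at 1.6 and 4.42 against 1.38 and 37.9, beside T23F2.4 and a copy of F46A8.7 with libraries listed at 0. In all, 212 genes had a log2 hypoxia ratio at least 1 higher in labelled elt-2 RNAi and 336 at least 1 lower. With 4 libraries this difference has no test. By list, the median difference was -0.60 for intestinal immune effectors, -0.54 for C-type lectins, -0.45 for digestive proteases, -0.43 for cuticle collagens, 0.46 for intestine markers, 0.49 for endoplasmic reticulum chaperones, 0.32 for cytosolic heat shock genes and 0.38 for sperm markers, each apart from random lists. The highest median difference was that of vitellogenins, 0.99 over 3 genes with 1 past 2-fold. It uses the normoxia library labelled elt-2 RNAi, the only one with values for vit-2, vit-5 and vit-6. This family was therefore not quantified alike in all libraries, and the vitellogenin difference cannot be read as a response. Smaller shifts that also stood apart were -0.26 for UDP-glucuronosyltransferases, -0.24 for epidermal antimicrobial peptides, -0.24 for fatty acid synthesis genes, -0.19 for glutathione S-transferases, -0.18 for beta-oxidation genes, -0.14 for antioxidant genes, -0.06 for citric acid cycle and oxidative phosphorylation genes and -0.01 for ribosomal protein genes. Of these differences, some depended on settings. With the length trend removed, antioxidant genes lay inside the random range (-0.09) and ribosomal protein genes turned sign (0.04). Epidermal antimicrobial peptides turned sign with no filter on low values (0.02), and sperm markers lay inside the range with a pseudocount of 0.1 RPKM (0.04). HIF-1-dependent genes (0.07, percentile 68.4) and iron and haem handling genes (0.05, percentile 59.3) lay inside the random range for this difference.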

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

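The tests of exchanged labels and of bacterial double-stranded RNA were chosen after the results they bear on were seen. The average effects of hypoxia and of RNAi were tested with limma, but their interaction has no test with 1 library per group, so each opposite movement below is a pair of values whose difference was not tested.

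Under hypoxia, 3 named genes went past 2-fold in opposite directions in the RNAi groups. The log2 hypoxia ratio was 3.58 in control RNAi and -3.67 in the libraries labelled elt-2 RNAi for fipr-20, 1.76 and -1.91 for C26F1.1, and -2.58 and 2.48 for F09C8.1. For RNAi, 4 named genes went opposite ways in normoxia and hypoxia. The log2 ratio of labelled elt-2 RNAi over control was 1.46 and -1.26 for Y38E10A.15, -5.96 and 1.48 for a copy of F46A8.7, 3.67 and -3.58 for fipr-20, and -3.66 and 1.40 for F09C8.1. Libraries listed at 0 enter the ratios of fipr-20 and F46A8.7, and both loci are little longer than a read of 100 bp. Endoplasmic reticulum chaperones stood apart below random lists in normoxia (median -0.12) and above them in hypoxia (0.33).

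The targeted gene elt-2 was higher in both libraries labelled elt-2 RNAi. Exchanged control and elt-2 RNAi labels would make intestinal genes higher there, and the tables argue against this, since the median of intestinal immune effectors was -1.01 in normoxia and -1.59 in hypoxia. The first of these only just passes the bound of -1 written for the test, and digestive proteases, at -2.46 and -2.32, point the same way. Reads from double-stranded RNA that the food bacteria make from the cloned part of elt-2 may raise its value, and the lower of the log2 ratios was 0.62. Values per gene do not show where on elt-2 the reads lie, so this cannot be told apart from a true increase of the transcript. A biological response of elt-2 to the RNAi was not tested.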

How the results depend on the processing

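The length trend and the removal of genes listed at 0 were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no replicate numbers link the groups, apart from the additive limma fit, which already compares oxygen levels within each RNAi group. No library could be left out either. Centring on the median gene, keeping loci that name several genes, requiring the status OK and removing the length trend left every one of the 15 counts within 1.5 times its main value, as did leaving out genes listed at 0 for the 12 counts run. Of the 94 list medians apart from random lists, 94 stayed apart when centred and 89 with the length trend removed. Lists not apart in the main setting were checked only with the length trend removed. With no filter on low values 88 stayed apart, 5 lay inside the random range and 1 turned sign. With a mean of at least 5 RPKM some of the 94 had under 3 loci and were not run. Of those run, 86 stayed apart and 4 lay inside. Lost with no filter were beta-oxidation genes for hypoxia in control RNAi (0.16), cytochrome P450s (-0.04) and UDP-glucuronosyltransferases (-0.05) for RNAi in normoxia, and antioxidant genes for RNAi in hypoxia (-0.07) and for the difference (-0.01). Lost at the higher mean were beta-oxidation genes for hypoxia in control RNAi (0.30), C-type lectins for hypoxia in labelled elt-2 RNAi (-0.14), ribosomal proteins for RNAi in hypoxia (-0.01) and epidermal antimicrobial peptides for the difference (-0.11). Others lost were neuron markers for RNAi in normoxia without the length trend (-0.14), cytochrome P450s for hypoxia in control RNAi with a pseudocount of 5 RPKM (0.22) and the ribosomal protein difference with loci naming several genes (-0.01). With the length trend removed, gluconeogenesis genes for hypoxia in labelled elt-2 RNAi (-0.22) and antioxidant genes for the difference (-0.09) were lost too. Sperm markers for the difference were lost with a pseudocount of 0.1 RPKM. The sign turned for ribosomal proteins in the RNAi effect in hypoxia (0.0164) and in the difference of hypoxia effects (0.0432) without the length trend, and for epidermal antimicrobial peptides in that difference with no low filter (0.0212).

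The order of counts here is hypoxia in control RNAi, hypoxia in labelled elt-2 RNAi, RNAi in normoxia, RNAi in hypoxia and the difference of hypoxia effects, each higher then lower. With a pseudocount of 5 RPKM they were 464 and 170, 528 and 191, 52 and 197, 88 and 327, and 89 and 147, the overlaps were 386 for hypoxia and 176 for RNAi, and limma called 51 genes for RNAi. At 4-fold they were 148 and 58, 193 and 81, 28 and 116, 38 and 218, and 26 and 53. A pseudocount of 0.1 moved RNAi in normoxia to 233 higher, and the difference to 358 and 507. A mean of at least 5 RPKM gave 655 higher for hypoxia in control RNAi, 70 higher for RNAi in normoxia, 125 and 354 for RNAi in hypoxia, and 124 and 185 for the difference, on fewer genes. With no filter limma called 2215 genes for hypoxia and 48 for RNAi, and without the trend 2182 and 0. A higher threshold or pseudocount lowers counts by construction, and the cause of the other shifts was not tested. Depth limits low genes most, and a pseudocount of 5 moved 75 of 90 named ratios by over 1.5-fold.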

Other observations

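Of 36 compared cytochrome P450 genes, 10 were at least 2-fold higher and 1 lower in control RNAi hypoxia (median log2 ratio 0.42, percentile 98.8), with cyp-32B1 at 4.21 and cyp-13A5 at 3.16. In the libraries labelled elt-2 RNAi, 9 were higher and 3 lower (0.32, percentile 97.4). With the length trend removed that median was 0.36 and stood apart (percentile 99.3). For RNAi the medians were -0.14 in normoxia (percentile 0.59) and -0.06 in hypoxia (percentile 13.7), with cyp-35A3 at -4.51 and -5.19, cyp-35C1 at -3.91 and -3.49 and cyp-13A5 at 1.90 and 1.96. The P450 median for RNAi in normoxia lay inside the random range with no filter on low values. The one for hypoxia in control RNAi did so with a pseudocount of 5 RPKM. UDP-glucuronosyltransferases had medians of 0.29 and 0.15 for hypoxia and of -0.17 (percentile 0.19) and -0.55 (percentile 0) for RNAi, with 15 of 45 at least 2-fold lower in labelled elt-2 RNAi hypoxia, ugt-18 at 17 RPKM in control RNAi hypoxia and 0.129 there. Their median for RNAi in normoxia lay inside the random range with no filter on low values. Glutathione S-transferases had medians of 0.06 and -0.14 for hypoxia and -0.08 (percentile 3.33) and -0.21 (percentile 0.19) for RNAi. Within them gst-4 was at -1.84 and -3.96, and gst-10 at -1.81 and -3.59, for hypoxia in the control and labelled elt-2 RNAi groups. Antioxidant genes had medians of -0.05 and -0.16 for hypoxia and of -0.09 (percentile 2.01) and -0.18 (percentile 0.355) for RNAi. The last of these lay inside the random range with no filter on low values.

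Glycolysis had a median of 0.05 under hypoxia in both RNAi groups, with T05D4.1 (aldo-1) at 1.71 and 1.68, gpd-3 at 1.16 and 1.43, gpd-4 at -0.98 and -0.85 and pfk-1.1 at -0.98 and -0.83, and of 0.10 and 0.13 for RNAi. Citric acid cycle and oxidative phosphorylation genes had medians of 0.17, 0.11, 0.04 and -0.05 in the 4 comparisons, with none past 2-fold. Of these only the last stood apart from random lists (percentile 0.22). With the length trend removed the first did too, at 0.08 (percentile 98.7). Gluconeogenesis, glyoxylate, trehalose and glycogen genes had medians of -0.33, -0.36, -0.08 and -0.06, of which only the second stood apart from random lists (percentile 0.98). With the length trend removed it was -0.22 and inside their range (percentile 11.3). The medians for RNAi then stood apart, at -0.14 in normoxia (percentile 0.83) and -0.20 in hypoxia (percentile 0.47). For hypoxia in control RNAi tps-2 was at 1.19, W05G11.6 (pck-1) at 0.64, tps-1 at 0.26, icl-1 at -0.02, pyc-1 at -0.29, gsy-1 at -0.37, R11A5.4 (pck-2) at -0.47, fbp-1 at -0.58, T22F3.3 (pygl-1) at -0.66 and gei-7 at -0.99. The 9 named members of this list matched 10 loci, so at least 1 name entered its median through more than 1 locus. Mitochondrial chaperones had medians of 0.09, 0.03, 0.17 and 0.15, hsp-6 being at 0.77 and clpp-1 at 0.42, dnj-10 at 0.20, ubl-5 at 0.09, hsp-60 at 0.03, lonp-1 at -0.02 and ZC376.7 (atfs-1) at -0.28 in the first. Autophagy genes had medians of 0.07, 0.02, 0.04 and 0.15, with the adaptor T12G3.1 (sqst-1) at 0.97 and 1.74 for hypoxia. Vacuolar ATPase subunits had medians of 0.08, 0.03, -0.05 and -0.08, histones of 0.11, 0.15, -0.08 and -0.05, and endoplasmic reticulum chaperones one of -0.37 for hypoxia in control RNAi. Both vacuolar ATPase medians for RNAi stood apart below random lists (percentiles 1.6 and 0.465), as did the chaperone median (percentile 0.935). GATA factors had medians of 0.94, 0.69, -0.08 and -0.33, with elt-4 at 1.55, elt-7 at 1.42, elt-3 at 0.47 and elt-1 at -0.24 in the first.

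The test of library scaling was chosen after the counts were seen. More genes were at least 2-fold higher than lower under hypoxia, by 2.67 times in control RNAi and 2.32 times in the libraries labelled elt-2 RNAi. Short genes had higher ratios, with a median of 0.30 in the shortest sixth and -0.27 in the longest in control RNAi, but with this trend removed the lower of the ratios was still 1.78. Centred on the median gene it was 2.97. Centring used the median gene among those with a mean of at least 5 RPKM. It raised both ratios, the other to 3.28. The median over all compared genes (0.01 in control RNAi and -0.01 in labelled elt-2 RNAi) is therefore not the offset removed. Neither the length trend nor an offset of the median gene thus accounts for the excess alone. A scaling difference that the median gene does not show stays open. A smaller germline share of the RNA may contribute, since germline markers had medians of -0.56 and -0.38 and muscle, neuron and epidermis markers were positive. Pharynx markers were at -0.30 over 3 genes within the random range, which leaves this open.

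Of the 1010 genes at least 2-fold higher in control RNAi hypoxia, 386 were under 2-fold in the libraries labelled elt-2 RNAi, 320 of them still above 0 and 195 at least 1.5-fold. Variation of genes with low values may account for part of this. The share under 2-fold was 22.2% among genes with a mean of at least 20 RPKM and 38.2% among all, in a test set beforehand. That mean includes the hypoxia library labelled elt-2 RNAi, which also decides whether a gene is under 2-fold. Genes high in that library pass the cut more easily, so the lower share cannot decide for this explanation. A second explanation, that these genes need ELT-2 in normoxia as well, predicted a lower RNAi ratio in normoxia, and their median was higher by 0.14 than that of the 624 genes past 2-fold in both. The normoxia library labelled elt-2 RNAi enters both the choice of genes and this value, which raises it with no effect, so although the bound written beforehand against this explanation was met, that bound was a poor choice and the explanation stays open. A dependence of the hypoxia response on ELT-2 is the biological explanation the design gives, and it was not tested, since the difference has no replicate. The reverse was seen too. Of the 1052 genes at least 2-fold higher in the libraries labelled elt-2 RNAi, only 624 were so in control RNAi. The 386 genes alone therefore do not show a response lost under the elt-2 RNAi label.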
